A study of Mus musculus with 9 samples.

How the data were processed

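Whole dorsolateral prostate from mice was measured on 9 one-colour Affymetrix gene arrays, 1 per animal as far as the labels show. Per the labels, the mice were 12 weeks old, on a mixed background of 80% C57BL/6 and 20% 129S1/SvImJ, and fell into 3 groups of 3 biological replicates: wild type, a prostate-specific knockout of Pten, and a prostate-specific double knockout of Pten and Pml made with the Pb-Cre4 transgene. Total RNA was extracted with QIAzol and labelled with biotin, per the labels. No batch, date or pairing of animals is given.

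The deposited values are log2 intensities that the authors had already normalized between arrays. The scale was read from the values, since no field states it. The method of summary, background correction and normalization is not given in the sources used here, and limma is the only tool in the submitters' processing notes, without a version. Array medians lay between 7.67 and 7.73, minima between 1.87 and 2.11, and maxima between 13.05 and 13.19. The values carry no centring of genes, but background and saturation cannot be read from them, and no detection call is given. The table held 13912 probe rows and 0 missing values; the rule that chose these probes is not given in the sources used here, and no probe named Pten. The raw image files were not analysed here.

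Probes were named with the platform annotation, which listed 10144 of them. A symbol for 1 gene was given for 9528 probes, several symbols for 616, and none for 3768. Entrez identifiers of 9502 probes matched the reference gene table, and 0 symbols needed an update. Genes are named by symbol as in the annotation, so Rigi appears as Ddx58. For the 180 genes with several probes, the probe with the highest mean over the 9 arrays was used, which left 9255 genes. Positions on chromosomes are not printed, because the deposited files name no genome build; the order of genes along chromosomes came from the reference gene table.

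Group means were fitted over all 9 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with statmod 1.5.0 loaded beside it. In the alternative with blocks, replicate number was added to that fit as fixed terms. The 3 contrasts tested were Pten knockout against wild type, double knockout against Pten knockout, and double knockout against wild type. Tests were two-sided. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over the 9255 genes, and each change is a difference of log2 means with its SE. With 3 arrays per group the smallest p of an exact permutation test is 0.1, so calls rest on the spread pooled across genes and groups. The number of arrays limits the precision of every value.

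Before the data were examined, 31 gene lists with 542 members were fixed for pathways and cell types, together with the comparisons, thresholds and alternatives. Of these members 353 were measured, and some cell type lists kept few. Measured were 2 of 21 members for T and NK cells, 5 of 14 for B and plasma cells and 2 of 14 for nerve and neuroendocrine cells. For skeletal muscle 3 of 13 were measured, for adipose tissue 4 of 12, for endothelium 5 of 13, for seminal vesicle 4 of 9 and for erythrocytes 1 of 9. Each list was tested with camera at its preset correlation of 0.01, which compares the members with all other genes, and p was adjusted over the 31 lists. The same test with a correlation estimated from the data, and fry, which asks whether the members move 1 way on balance, were run beside it. Genes are named by a rule fixed at the same time: Pten and Pml, the 8 genes with the largest change each way among called genes whose arrays did not overlap between groups, and up to 4 members of each list with the smallest p. Any other gene is named as chosen after its values were seen.

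The overlap of the 2 comparisons against wild type was set against the count expected if the calls were independent and against 100 simulated sets with shared controls and no change. The fit was tested on simulated data with 200 genes shifted by log2 0.5, 1 or 2. At a shift of 1 it called 94.0% of the shifted genes in the set labelled Pten knockout against wild type. It called 98.5% in that labelled double against Pten knockout and 92.5% in that labelled double knockout against wild type. At 0.5 it called 62.7%, 56.7% and 53.7%, with 10 or 11 false calls in each. The sets had independent normal noise with the same spread in all groups, and far fewer changed genes than were called against wild type. Their percentages are therefore not the power of the real comparisons. Alternatives covered normalization, the probe per gene, leaving out the dimmest genes (the lowest tertile by mean over the arrays), moderation, array weights, the threshold, the groups in the fit, blocks by replicate number, the list test and leaving out each of the 9 arrays in turn. An alternative with other pseudocounts was not run, because the values were already on the log scale. Probes with no symbol or with several were left out of the gene counts.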

Results

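The series measured transcript levels in the dorsolateral prostate of 12-week-old mice on 9 arrays. The 3 groups of 3 mice were wild type, Pten knockout and Pten Pml double knockout, and the labels call the tissue of both knockouts tumour. Median log2 intensity was 7.72, 7.67 and 7.69 on the wild type arrays, 7.73, 7.70 and 7.73 on the Pten knockout arrays, and 7.73, 7.69 and 7.73 on the double knockout arrays. Arrays of 1 group resembled each other closely across the 9255 genes, with Pearson r of 0.980 to 0.990, where genes are not independent replicates. Between Pten and double knockout arrays r was 0.964 to 0.979, and between wild type and either knockout it was 0.743 to 0.778. The first principal component held 87.6% of the variance and parted wild type from both knockouts, and the second held 4.21% and parted the knockouts from each other.

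**Figure D1:**
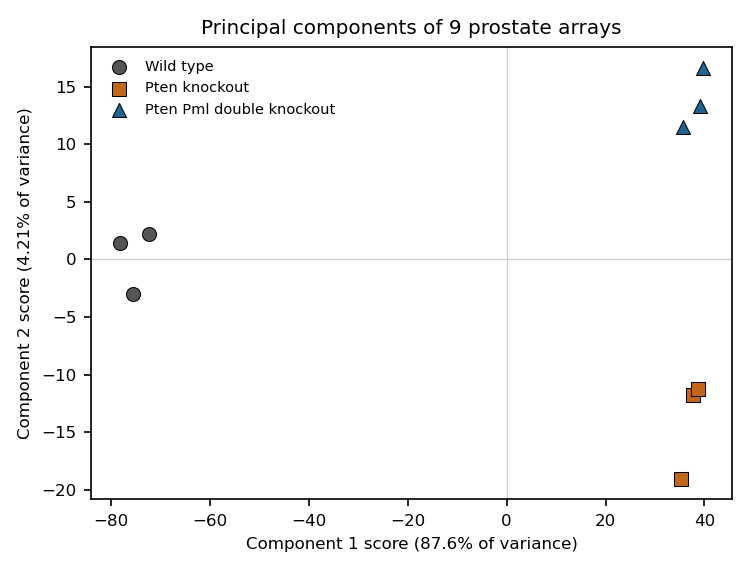
Each point is 1 array, placed by its scores on the first and second principal components of the 9255 genes (log2 units), with the share of variance on each axis (87.6% and 4.21%). The 3 wild type arrays lie between -78.2 and -72.4 on the first axis and the 6 knockout arrays between 35.3 and 39.7, and on the second axis the Pten knockouts lie between -19.0 and -11.3 and the double knockouts between 11.5 and 16.6.

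Pml, the targeted gene that encodes the scaffold protein of nuclear bodies, was higher in Pten knockout than in wild type prostates (log2 9.38 ± 0.18 against 8.05 ± 0.31, SD, n = 3), a change of 1.33 (SE 0.16, limma adjusted p = 6.0e-05). In double knockout prostates it stood at 8.18 ± 0.14, which was below the Pten knockout level by a log2 change of -1.20 (SE 0.16, adjusted p = 0.0072). Against wild type the double knockout differed by 0.13 (SE 0.16, adjusted p = 0.489), which did not pass the test. The arrays read whole tissue, and whether the Pml probe covers the deleted part of the gene is not given in the sources used here. Pten, the other targeted gene, which encodes the lipid phosphatase that opposes PI3K, has no probe in the deposited table.

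Pten knockout was compared with wild type to ask how prostate tissue labelled as lacking Pten differed at this age. Of 11 measured prostate secretory products, 9 fell and 2 rose: Msmb, a secreted protein of the prostate, went from log2 11.32 ± 0.05 to 8.12 ± 0.42 (SD, n = 3), a change of -3.20 (SE 0.21), and Azgp1, a secreted zinc-binding glycoprotein, changed by -3.18 (SE 0.14). Genes of interferon response rose in all 21 measured members, such as Rtp4, a chaperone of membrane receptors, from 5.25 ± 0.60 to 9.96 ± 0.13. Markers of luminal progenitor-like epithelium rose in 10 of 10, with the keratin Krt4 going from 5.97 ± 0.24 to 11.82 ± 0.03. Smooth muscle genes fell in 13 of 13, with the smooth muscle myosin Myh11 going from 11.50 ± 0.06 to 9.32 ± 0.16. Each member counted passed limma's test over the 9255 genes.

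Of 9255 genes, 6438 (69.6%) changed, 3669 higher and 2769 lower, and 2208 changed at least 2-fold, 1425 higher and 783 lower (1123 without the dimmest genes, 3339 over every probe). The excess of higher genes depended on scaling and on the probes kept. Quantile normalization gave 3356 higher and 3050 lower, and every probe tested on its own gave 4524 and 4244. The groups did not overlap for 74.9% of genes, where chance gives 10%. Shares of genes in each comparison, and camera's setting of members against all other genes, refer to the genes in the deposited table. The rule that chose those genes is not given, so the shares may not hold for all transcripts. The largest rises were in Gsdmc2 and Gsdmc3, of the pore-forming gasdermin family, by 7.98 (SE 0.10) and 7.57 (SE 0.15), followed by Lypd8 (6.92), Sval1 (6.73), the GABA receptor subunit Gabrp (6.58), the chemokine Cxcl15 (6.45), Clec2e (6.39) and Wfdc2 (6.38). The largest falls were in Pate14 by a log2 change of -7.30 (SE 0.93), Glb1l3 (-7.17), 5033404E19Rik (-6.59), the defensin gene Defa39 (-6.40), Ms4a5 (-6.25), C1rb (-6.09), Syt10 (-6.01) and the basement membrane collagen Col4a6 (-5.72). Adjusted p for these 16 genes ran from 3.0e-10 to 8.7e-05. Many of them stood near the lower end of the scale in 1 of the groups, and without a detection call the floor that limits the size of such a change is unknown.

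Among lists of immune and stress genes, all 21 interferon response genes rose (21 adjusted over the list alone), with a median of 2.82 and a camera adjusted p of 1.31e-06. That call was lost at adjusted p = 0.461 with an estimated correlation. Examples were the transcription factor Irf9 (1.94), the RNA sensors Ddx58 (2.86) and Ifih1 (1.88), and Rtp4 (4.71). Of the genes for MHC class I antigen presentation, 12 of 14 rose (12 adjusted over the list alone), with Nlrc5, their transactivator, up by 2.32, H2-Q4 by 3.14 and Irf1 by 1.49 (camera adjusted p = 1.56e-04; adjusted p = 0.461 with an estimated correlation). All 15 macrophage markers rose (15 adjusted over the list alone), among them the lipopolysaccharide co-receptor Cd14 (4.99), the mannose receptor Mrc1 (2.80), Fcgr1 (2.42) and Cd68 (2.30). Camera gave adjusted p = 2.94e-05 for them, against adjusted p = 0.476 with an estimated correlation. For MHC class II and dendritic cells 6 of 7 rose (6 adjusted over the list alone), with H2-Aa at 2.36 and the integrin Itgax at 2.23 (camera adjusted p = 0.0362; adjusted p = 0.461 with an estimated correlation). Quantile normalization ended that call (adjusted p = 0.0564), as did leaving out the dimmest genes (0.0688), within a range of 2.9e-05 to 0.461 over its alternatives. Genes of senescence-associated secretion rose in 13 of 13 (13 adjusted over the list alone), with the neutrophil-attracting chemokines Cxcl5 (6.01) and Cxcl2 (5.24) and the cytokine Il1b (2.82). Their camera adjusted p was 5.6e-04, against adjusted p = 0.285 with an estimated correlation.

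Genes of cell proliferation rose in 29 of 29 (29 adjusted over the list alone), with a median of 1.25, including the replication helicase subunits Mcm3 (1.59) and Mcm7 (1.16) and the cyclin Ccna2 (1.84). Camera gave adjusted p = 6.77e-06, and adjusted p = 0.577 with an estimated correlation. In the p53 response and cell cycle arrest list 10 of 14 rose and 3 fell (10 and 3 adjusted over the list alone), with the cyclin-dependent kinase inhibitors Cdkn1a (2.72) and Cdkn2b (2.47) and the kinase Plk2 (2.69) among the risen. Its camera adjusted p was 0.0480 (adjusted p = 0.285 with an estimated correlation), and it lost the call in 7 of 19 alternatives, among them leaving out double knockout replicate 1 (0.0578), 2 (0.0519) or 3 (0.0672), in a range of 1.17e-06 to 0.285. Hypoxia and glycolysis genes rose in 13 of 15 (13 higher and 1 lower adjusted over the list alone), with the oxygen sensor Egln3 (3.54), the phosphofructokinases Pfkl (1.47) and Pfkp (1.32) and the pyruvate kinase Pkm (0.95). Camera gave adjusted p = 0.0069, and adjusted p = 0.577 with an estimated correlation. All 10 luminal progenitor-like markers rose (10 adjusted over the list alone), with a median of 3.52, among them Ly6d (5.44) and the stress-induced Nupr1 (4.38). Their camera adjusted p of 2.94e-05 became adjusted p = 0.285 with an estimated correlation.

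Of the genes for the unfolded protein response and folding in the endoplasmic reticulum, 16 of 17 fell and 1 rose (16 and 1 adjusted over the list alone), with Creld2 (-1.80), the disulfide isomerase Pdia6 (-1.56), Herpud1 (-1.40) and Sdf2l1 (-1.38). Camera gave adjusted p = 1.2e-05, and adjusted p = 0.285 with an estimated correlation. Prostate secretory products fell in 9 of 11 and rose in 2 (9 and 2 adjusted over the list alone), with a median of -3.18. The defensin gene Defb50 changed by -2.65, and Mfge8, a secreted bridge for engulfment of dying cells, rose by 1.96 (camera adjusted p = 0.0128; adjusted p = 0.285 with an estimated correlation). Smooth muscle genes, 13 of 13 lower (13 adjusted over the list alone), had a median of -1.76, with the tropomyosin Tpm2 (-2.90), the myosin kinase Mylk (-2.75) and the actin-binding Synpo2 (-2.67) among them. Camera gave adjusted p = 2.9e-06, and adjusted p = 0.285 with an estimated correlation. All 3 skeletal muscle markers measured, of 13 fixed, fell (3 adjusted over the list alone). The actin Acta1 changed by -3.41, the troponin Tnnc2 by -2.00 and the creatine kinase Ckm by -1.49. Their camera adjusted p of 0.0152 became adjusted p = 0.285 with an estimated correlation, and 0.118 without the dimmest genes.

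The other 18 lists were not called by camera, and counts adjusted over the list alone were equal to those given here except where stated. Cholesterol synthesis genes rose in 10 of 15 and fell in 1 (adjusted p = 0.124), with Cyp51 (1.80), Fdft1 (1.76) and Nsdhl (1.63), and genes of fatty acid and triglyceride synthesis rose in 11 of 18 and fell in 4 (0.210). Fatty acid oxidation genes rose in 5 of 10 and fell in 3 (0.747), with the coactivator Ppargc1a up by 2.48. ERK MAPK output genes rose in 8 of 14 and fell in 4 (0.503), with the phosphatase Dusp4 up by 2.19. FOXO targets rose in 6 of 17 and fell in 6 (0.518), with the death ligand Tnfsf10 up by 5.74 and the transcription factor Klf15 changed by -3.78. Androgen response genes rose in 6 of 15 and fell in 7 (0.757), with the TGF-beta inhibitor Pmepa1 up by 3.51 and the peptidase Mme changed by -1.92. The median of the FOXO list was -0.14 with a mean of 0.09, and that of the androgen list 0.04 with a mean of -0.02, while camera pointed down for both. Luminal markers rose in 7 of 10 and fell in 2 (0.131), with Krt8 up by 1.19, and basal markers did so in the same numbers (0.232), with Krt17 up by 3.58.

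Neutrophil markers rose in 9 of 14 and fell in 1 (0.133), with the iron-binding Ltf up by 5.0. Only 2 of the 21 fixed T and NK cell markers were measured, and both rose (0.124), the granzyme Gzmb by 1.99 and Nkg7 by 1.98. B and plasma cell markers rose in 3 of 5 and fell in 2 (0.862), with the immunoglobulin genes Jchain up by 4.77 and Ighm by 4.45, and Derl3, a gene of endoplasmic reticulum degradation, changed by -4.74. Genes of fibroblasts and extracellular matrix rose in 7 of 16 and fell in 3 (0.927), and those of epithelial-mesenchymal transition rose in 5 of 9 and fell in 2 (0.705). Endothelial markers fell in 2 of 5 (1 adjusted over the list alone; 0.610), nerve and neuroendocrine markers in 1 of 2 (0.518), and adipose markers in 2 of 4, with 1 higher (0.437). Camera pointed down for the endothelial list at a median of 0.08 and a mean of -0.13, and for the nerve list at a median and mean of 0.21. The only erythrocyte gene measured, Slc4a1, was lower by limma's test over all genes, with a change of -0.42 (camera adjusted p = 0.503 for the list). None of the 4 seminal vesicle genes passed the test (camera adjusted p = 0.533), and Svs2, a secreted clotting protein, spread widely in wild type prostates (6.74 ± 2.61, SD, n = 3). With an estimated correlation 0 of the 31 lists were called and 3 had an unadjusted p under 0.05, while fry called 27.

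Double knockout was compared with Pten knockout to ask what differed where the labels add a knockout of Pml to that of Pten. The array showed Pml below its Pten knockout level (8.18 against 9.38) but not below wild type (8.05). Pbsn, the secreted androgen-dependent protein probasin, fell from log2 8.74 ± 0.71 to 4.92 ± 0.93 (SD, n = 3), a change of -3.82 (SE 0.45, adjusted p = 0.0037), and Msmb fell from 8.12 ± 0.42 to 5.22 ± 0.34, a change of -2.91 (SE 0.21, adjusted p = 2.8e-04). Spink1, a secreted inhibitor of trypsin-like proteases, rose from 4.49 ± 0.50 to 8.73 ± 1.03, a change of 4.24 (SE 0.66, adjusted p = 0.0163), against a wild type level of 7.97. Of 13 smooth muscle genes 6 were lower than in Pten knockout prostates (camera adjusted p = 6.8e-16; adjusted p = 0.0937 with an estimated correlation), with Myh11 at 7.90 ± 0.22 against 9.32 ± 0.16. The C-type lectin gene Clec2e, which was higher in Pten knockout than in wild type prostates, stood at 3.81 ± 0.37 against 9.82 ± 0.19, near its wild type level of 3.43.

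Between the knockouts 120 of 9255 genes (1.30%) changed, 38 higher and 82 lower, 57 of them at least 2-fold (31 without the dimmest genes, 104 over every probe), and 999 had an unadjusted p under 0.05. The groups did not overlap for 18.6% of genes, where chance gives 10%. Of the 82 lower genes, 38 had been higher in Pten knockout than in wild type prostates, 37 lower and 7 not called. Of the 38 higher genes, 6 had been higher, 25 lower and 7 not called. Over all 9255 genes, 3669 were higher and 2769 lower in Pten knockout than in wild type prostates. The Pten knockout arrays enter both comparisons with opposite signs, so their noise favours opposite calls. Besides Spink1, the largest rises were in D730005E14Rik (4.16, SE 0.19, adjusted p = 1.0e-05), the sialyltransferase gene St6galnac2 (2.98), Wdr72 (2.78), Crabp1, a binding protein for retinoic acid (2.54), Gm3893 (2.33), the secretoglobin gene Scgb2b27 (2.31) and Gm1966 (2.03). The 3 probes for Gm3893 all read higher in double than in Pten knockout prostates. After Clec2e (-6.01, SE 0.18, adjusted p = 6.9e-07), the largest falls were in Tcaf3, of a family that binds TRPM8 channels (-4.56), the prostate transglutaminase gene Tgm4 (-3.90), Pbsn, the small nucleolar RNA Snord13 (-3.66), Pate9 (-3.28), Msmb and Trim12c (-2.50). Leaving out Pten knockout replicate 1, 2 or 3 left 61, 63 or 74 changed genes, of which 56, 58 and 63 were among the 120. Leaving out double knockout replicate 1, 2 or 3 left 91, 61 or 85. Each of these fits had fewer samples, so a weight of particular arrays cannot be told apart from a loss of power. The calls of Scgb2b27 (lost in 11 of 16 alternatives), Tgm4 (10 of 17), Tcaf3 and St6galnac2 (7 of 17 each), Spink1 (4 of 16), Pate9 (3 of 17) and Crabp1 (2 of 16) also depended on the setting, with adjusted p of up to 0.146, 0.162, 0.102, 0.0767, 0.0741, 0.0584 and 0.0580.

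**Figure D2:**
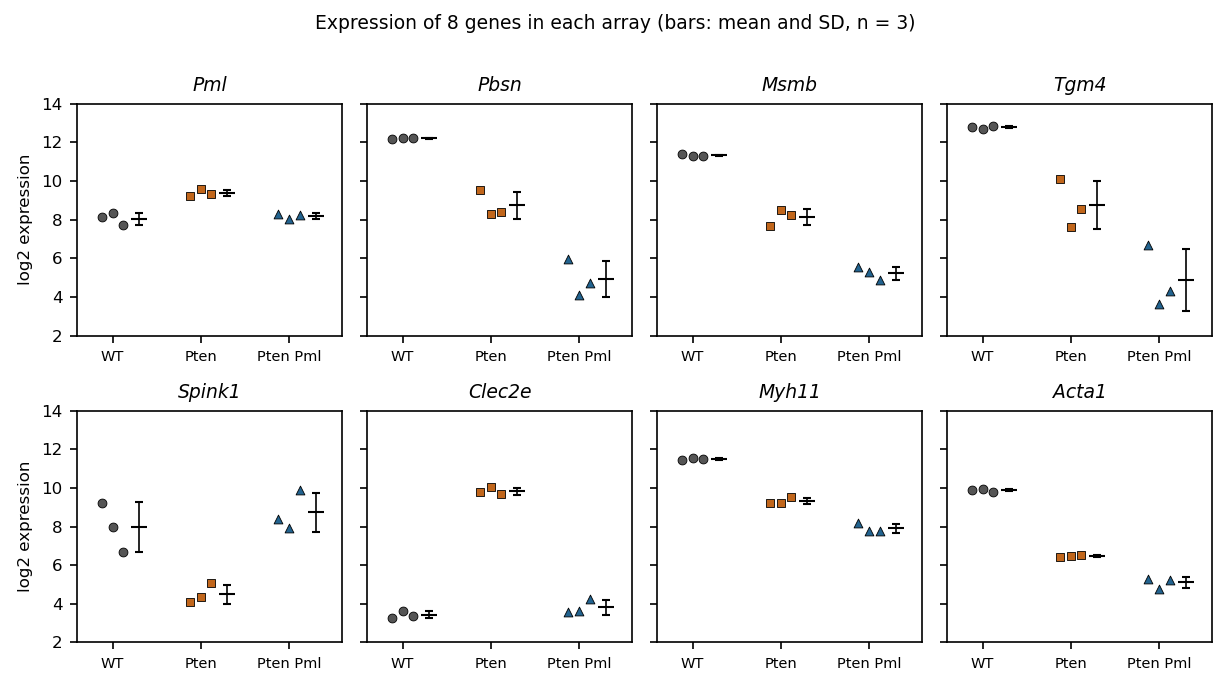
Each point is 1 array's log2 expression of 1 of 8 named genes in wild type (WT), Pten knockout (Pten) and double knockout (Pten Pml) prostates, and the black bars beside the points are the mean and SD of the 3 arrays. The mean of Msmb is 11.32 in wild type, 8.12 in Pten knockout and 5.22 in double knockout prostates, while that of Pml is 8.05, 9.38 and 8.18.

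Smooth muscle genes were lower in 6 of 13 (10 adjusted over the list alone), with a median of -0.76. Besides Myh11 (-1.41) they included the calponin gene Cnn1 (-1.30), the adhesion protein gene Pgm5 (-1.20) and Mylk (-0.96), and camera gave adjusted p = 6.8e-16, against adjusted p = 0.0937 with an estimated correlation. Skeletal muscle markers were lower in 2 of 3 (3 adjusted over the list alone), Acta1 by a change of -1.36 and Tnnc2 by -0.83, while Ckm at -0.92 did not pass over all genes. Their camera adjusted p of 3.2e-06 became adjusted p = 0.0661 with an estimated correlation. Over the same arrays the mean of the fibroblast genes differed by 0.09, with an SD of 0.51 among double knockouts, and 0 of 16 passed limma's test, 1 at an unadjusted p under 0.05 (camera adjusted p = 0.546, fry 0.960). The direction turned on single arrays: camera called the list downward without double knockout replicate 2 (adjusted p = 0.0174) and upward without replicate 3 (2.1e-05).

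Prostate secretory products were lower in 4 of 11 and higher in 1 (5 and 4 adjusted over the list alone), with Pbsn, Msmb and Defb50 (-2.41) lower and Spink1 higher. Camera gave the list adjusted p = 0.0605, which passed in 8 of 19 alternatives, in a range of 0.0011 to 0.519; these included leaving out Pten knockout replicate 1 (0.0340) or 3 (0.0207) and double knockout replicate 1 (0.0258) or 3 (0.0242). In the androgen response list, Ndrg1, a stress-responsive differentiation gene, rose by 0.77, and Pbsn and the serine protease Tmprss2 (-0.58) fell, 3 of 15 members (3 adjusted over the list alone; camera adjusted p = 0.413).

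Camera called 6 more lists in which 0 members passed limma's test over all genes. Hypoxia and glycolysis genes had a median of 0.22, all 15 above 0 and 3 higher adjusted over the list alone, with 6 at an unadjusted p under 0.05, among them the angiogenic factor Vegfa at 0.37 and the glycolytic activator Pfkfb3 at 0.75. Their camera adjusted p was 3.7e-05, against adjusted p = 0.519 with an estimated correlation and fry at 0.148. Cholesterol synthesis genes had a median of 0.20, with 14 of 15 above 0, Sqle at 0.42 among them, and 1 at an unadjusted p under 0.05, Hsd17b7 at 0.39 (0 adjusted over the list alone). Camera gave adjusted p = 0.0011, against adjusted p = 0.60 with an estimated correlation and fry at 0.378. Folding genes of the endoplasmic reticulum had a median of -0.17 (3 at an unadjusted p under 0.05, 0 adjusted over the list alone), with camera at 0.0045, against adjusted p = 0.60 with an estimated correlation, fry at 0.199 and camera at 0.0826 without double knockout replicate 2. Genes for MHC class II and dendritic cells had a median of -0.40, with 2 lower adjusted over the list alone and 2 at an unadjusted p under 0.05. Camera gave them adjusted p = 0.0123, against adjusted p = 0.519 with an estimated correlation and fry at 0.175. FOXO targets had a median of 0.14 (5 at an unadjusted p under 0.05, 0 adjusted over the list alone), with camera at 0.0254, against adjusted p = 0.290 with an estimated correlation and fry at 0.0629. Without Pten knockout replicate 3 camera gave 0.122 for them, and without double knockout replicate 1 it gave 0.0530. Fatty acid oxidation genes had a median of 0.11 (2 at an unadjusted p under 0.05, 0 adjusted over the list alone) and camera at 0.0482, against adjusted p = 0.550 with an estimated correlation. That call was lost in 10 of 19 alternatives, among them leaving out Pten knockout replicate 1 (0.150) or 2 (0.138), double knockout replicate 2 (0.0826) or 3 (0.0869), or wild type replicate 1 (0.0509) or 2 (0.0543).

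Lists of proliferation (camera adjusted p = 0.728), interferon response (0.870), senescence-associated secretion (0.415), p53 response (0.573) and fatty acid synthesis (0.849) were not called between the knockouts, and 0 of their members passed limma's test over all genes. Without Pten knockout replicate 1, camera called the proliferation list downward (0.0381). At an unadjusted p under 0.05 they had 1, 3, 4, 3 and 2 members, with medians of -0.05, -0.00, -0.06, 0.01 and 0.02; the mean was 0.02 for the interferon list and -0.03 for the p53 list. Adjusted over the list alone, 1 gene of the p53 list, the death receptor Fas at -0.54, was lower. Genes of ERK MAPK output (median -0.15, camera adjusted p = 0.403) had 0 passing members and 3 at an unadjusted p under 0.05, such as the ERK phosphatase Dusp6 at -0.34. Macrophage markers had a median of 0.15 (camera adjusted p = 0.182), with 0 passing and 3 at an unadjusted p under 0.05, and were called upward without double knockout replicate 1 (0.0328) or 3 (0.0344). B and plasma cell markers had a median of -0.33, with 0 of 5 passing and 1, Jchain at -1.90, lower adjusted over the list alone. Camera gave them adjusted p = 0.0660, which passed in 3 of 19 alternatives, among them leaving out double knockout replicate 3 (0.0344). Without that array camera also called the lists of MHC class I (0.0127), basal epithelium (0.0173) and neutrophils (0.0216) downward. With an estimated correlation 0 of the 31 lists were called and 3 had an unadjusted p under 0.05, and fry called 3.

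**Figure D3:**
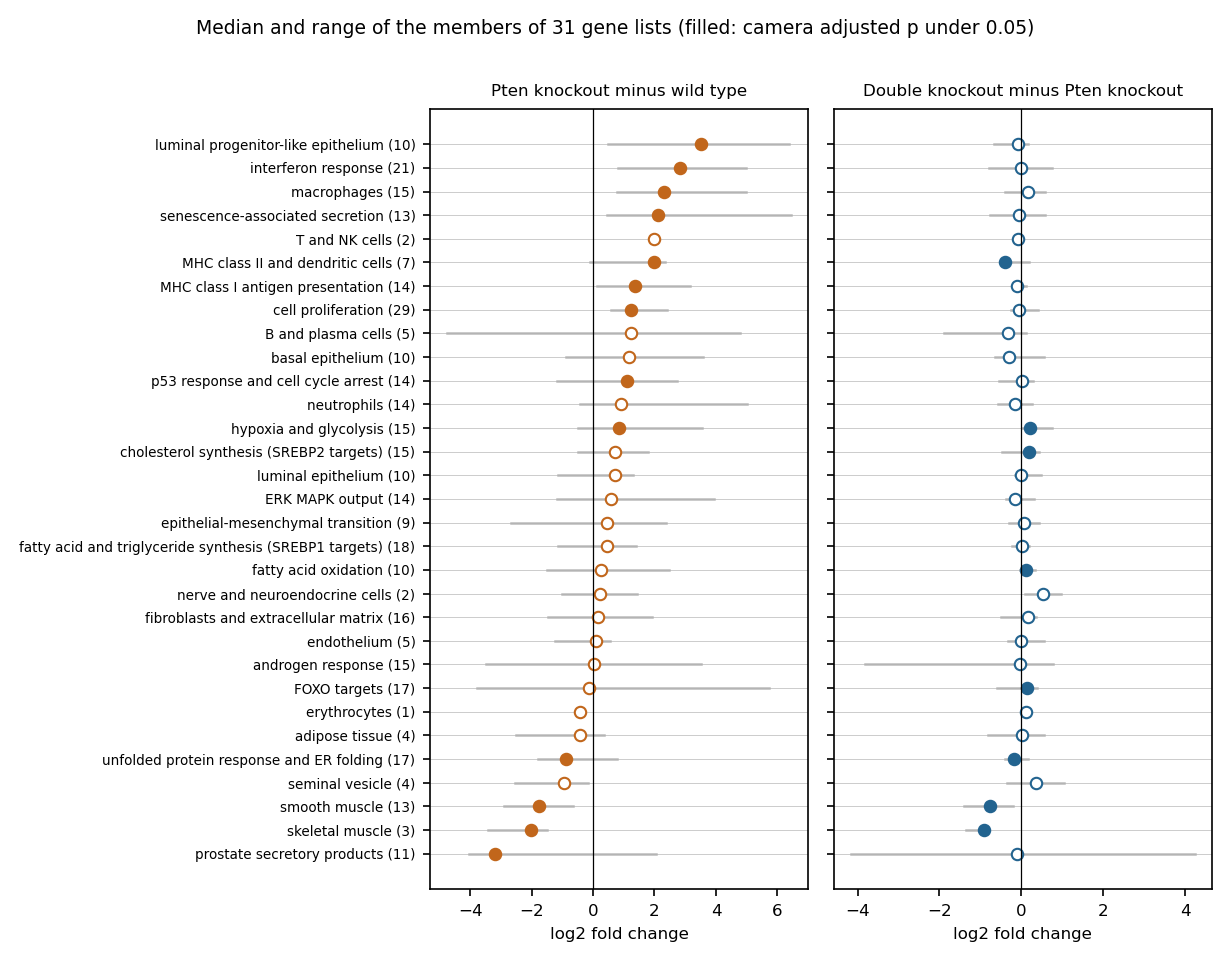
For each of the 31 gene lists (measured members in brackets), the point is the median log2 fold change of its members and the grey line their range, in Pten knockout against wild type (left) and double against Pten knockout (right), and filled points mark lists that camera called at its preset correlation. The median of the interferon list is 2.82 on the left and -0.00 on the right, and that of the smooth muscle list is -1.76 and -0.76; the axes of the panels differ in range.

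Double knockout was compared with wild type to ask how tissue labelled as lacking both genes differed from normal prostate. Of 11 prostate secretory products 8 fell and 2 rose (camera adjusted p = 0.0130; adjusted p = 0.301 with an estimated correlation), with Tgm4 at log2 4.87 ± 1.60 against 12.79 ± 0.07 (SD, n = 3), a change of -7.92 (SE 0.77), and Pbsn at 4.92 ± 0.93 against 12.22 ± 0.02, a change of -7.30 (SE 0.45). The gasdermin genes Gsdmc2 and Gsdmc3 rose by 7.83 (SE 0.10) and 7.08 (SE 0.15). All 21 interferon response genes, 15 macrophage markers, 29 proliferation genes and 10 luminal progenitor-like markers rose, and all 13 smooth muscle genes fell, each by limma's test over all genes. Of 9255 genes, 6471 (69.9%) changed, 3721 higher and 2750 lower, 2214 of them at least 2-fold (1139 without the dimmest genes), and the groups did not overlap for 72.7%, where chance gives 10%. Here too the excess of higher genes narrowed under quantile normalization, to 3411 higher and 2963 lower.

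The other large rises were in the protease inhibitor Mug1 (6.58), Gm12888 (6.42), Lypd8 (6.41), Cxcl15 (6.23), Wfdc2 (6.02) and Hsd11b2, which inactivates glucocorticoids (5.99). The other large falls were in Pate14 (-8.65), Ms4a5 (-8.37), 9530053A07Rik (-8.10), Glb1l3 (-7.96), C1rb (-7.41) and Tcaf3 (-7.41). Camera called 12 lists, 8 up and 4 down, of which 0 were called with an estimated correlation; 3 then had an unadjusted p under 0.05, and fry called 24.

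Interferon response genes had a median of 2.84 (21 of 21 higher adjusted over the list alone; camera adjusted p = 7.8e-07; adjusted p = 0.453 with an estimated correlation), with Rtp4 up by 4.71. Macrophage markers had a median of 2.50 (15 of 15 adjusted over the list alone; camera adjusted p = 2.0e-05; adjusted p = 0.453 with an estimated correlation), with Cd14 up by 4.62. Proliferation genes had a median of 1.19 (29 of 29 adjusted over the list alone; camera adjusted p = 7.4e-06; adjusted p = 0.594 with an estimated correlation). Luminal progenitor-like markers had a median of 3.46 (10 of 10 adjusted over the list alone; camera adjusted p = 4.0e-05; adjusted p = 0.301 with an estimated correlation). Genes for MHC class I antigen presentation rose in 13 of 14 (13 adjusted over the list alone), with camera at 2.9e-04 and adjusted p = 0.453 with an estimated correlation. Senescence-associated secretion rose in 12 of 13 (12 adjusted over the list alone), with camera at 8.6e-04 and adjusted p = 0.301 with an estimated correlation. Hypoxia and glycolysis genes rose in 13 of 15 (14 adjusted over the list alone), Egln3 by 4.13, with camera at 3.9e-04 and adjusted p = 0.453 with an estimated correlation. Cholesterol synthesis genes rose in 10 of 15 and fell in 1 (10 and 1 adjusted over the list alone), Cyp51 by 2.0 and Nsdhl by 1.98, with camera at 0.0411 and adjusted p = 0.667 with an estimated correlation. That call was lost in 5 of 19 alternatives, among them leaving out double knockout replicate 2 (0.0627) or 3 (0.0532).

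Smooth muscle genes had a median of -2.70 (13 of 13 lower adjusted over the list alone; camera adjusted p = 1.8e-07; adjusted p = 0.301 with an estimated correlation), with Mylk at -3.70 and Myh11 at -3.59. Folding genes of the endoplasmic reticulum fell in 15 of 17 and rose in 1 (15 and 1 adjusted over the list alone), Creld2 by a change of -1.97, with camera at 4.5e-06 and adjusted p = 0.301 with an estimated correlation. All 3 skeletal muscle markers measured, of 13 fixed, fell (3 adjusted over the list alone), Acta1 by a change of -4.77. Camera gave them adjusted p = 0.0060, against adjusted p = 0.301 with an estimated correlation. Without the dimmest genes, camera gave 0.10 for them. Secretory products fell in 8 of 11 and rose in 2 (8 and 2 adjusted over the list alone), Msmb by a change of -6.10 and Defb50 by -5.05, with camera at 0.0130 and adjusted p = 0.301 with an estimated correlation. Lists of p53 response (0.0693) and of MHC class II and dendritic cells (0.0891), called in Pten knockout against wild type, missed camera's threshold here.

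Both knockouts departed from wild type in similar ways: 5943 genes changed in the same direction in both comparisons, 3423 higher and 2520 lower, where independent calls would give 1475 and 823. Opposite calls numbered 8, while 487 genes were called in the Pten knockout alone and 520 in the double knockout alone, a difference that was tested directly only by the comparison of the knockouts. The changes of all genes correlated across genes with Pearson r = 0.969, against a median of 0.501 in 100 simulated sets with shared wild type arrays and no change. In those sets at most 0 genes were called in both by limma. Few calls can arise where no gene was changed, so that count is no measure of the overlap to expect here. The covariance of the changes was 1.33, against 0.0114 in the simulated sets. The 3 wild type arrays could not be split into parts of at least 2, so part of the excess over independence may come from the shared controls. In the simulated sets, which had independent noise, that part of the covariance was 0.0114, against 1.33 observed. For the count of shared calls it was not measured.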

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

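The count over the whole chromosome of Pml, the count with members of a gene family taken once, and the tests of the smooth muscle genes, with and without single arrays, were chosen only after the results were seen. Probes without a gene name lay outside the gene comparisons and changed in numbers of their own in an every-probe fit with limma: of 3768, 2013 changed in Pten knockout against wild type (680 higher and 1333 lower), 51 in double against Pten knockout (16 higher and 35 lower, with log2 changes of -3.54 to 3.71), and 1973 in double knockout against wild type (642 higher and 1331 lower). Of 616 probes with several gene names, 372, 13 and 384 changed in the same order. Among probes with 1 gene name 67.0%, 0.934% and 67.3% changed, against 53.4%, 1.35% and 52.4% of probes with no name.

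Genes that differed between double and Pten knockout prostates lay near each other in gene order: outside the neighbourhood of Pml, 38 of 116 had another changed gene within 5 measured genes, against a median of 14 and a highest of 34 in 10000 random sets matched on mean level (share 1e-04, the smallest these sets can give), and 34 did with members of a gene family taken once. Examples, named after their values were seen, were the neighbours Sun2 (0.61), D730005E14Rik (4.16), Apobec3 (0.62), Cbx7 (1.75) and Rpl3 (-1.93), and the neighbours Colgalt1 (-1.12), B3gnt3 (-0.93), Zfp709 (-0.65) and Cyp4f18 (-1.42). Blocks of DNA from 1 of the parent strains of this mixed background, shared by chance within a genotype, are a candidate explanation for such groups, while neighbours that change together whatever the comparison stay open: as many genes with the smallest p in Pten knockout against wild type gave 19 with a near neighbour, against a median of 14 (share 0.146). For strain DNA around the targeted Pml gene, 2 of the 50 nearest measured genes changed (Rcn2 and Tspan3), against 0.640 by chance (exact hypergeometric p = 0.134). Over the whole chromosome 11 of 545 did, against 6.97 (exact hypergeometric p = 0.0888). The nearest changed genes beyond the 50 were Crabp1, Colca2 and Il18 (-30, -44 and -55 measured genes from Pml), and Car12, Aph1c and Wdr72 (53, 54 and 85). Crabp1 and Wdr72 were among the largest rises between the knockouts. These genes were named after their values were seen, and no window between the 50 genes and the chromosome was tested. Counts this small leave strain DNA around Pml open. An effect of the Pml knockout on the changed genes stays open too, as untested, since no genotype of the animals was analysed here.

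Spink1 was higher and Pbsn, Msmb and Tgm4 were lower in double than in Pten knockout prostates. A larger share of ventral lobe in the tissue may give such a mix, because Spink1 and Sbp are ventral lobe products in mice. Sbp, named after its values were seen, differed by 1.49 (SE 0.57), which goes with that explanation in size but did not pass the test (adjusted p = 0.365). It stays open, as do a change of the secretory cells through the Pml knockout and the state of the tissue, both untested.

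Smooth muscle genes were lower in double than in Pten knockout prostates by a mean of -0.75. A lower share of all stroma is argued against as the whole cause: the smooth muscle mean minus the fibroblast mean differed by -0.84 (SD 0.06 among Pten and 0.48 among double knockout arrays), with each double knockout array below each Pten knockout array. The mean of fibroblast genes differed by 0.09, a value that rested on single arrays: without double knockout replicate 2 it was -0.16 (smooth muscle -0.73) and camera called the list lower (adjusted p = 0.0174), and without replicate 3 it was 0.34 and the list was called higher (2.1e-05). The difference between the lists stayed at -0.57 to -1.01 whichever of the 6 arrays was left out, so a share of the fall that goes with all stroma stays open. Less muscle of the surrounding tissue carried over in dissection stays open, since skeletal muscle markers were also lower by a mean of -1.03, though both muscle lists deviated the same way from their group means in only 3 of 6 arrays. A loss of smooth muscle, or of its gene products, around the glands through the Pml knockout stays open too, as untested.

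For each comparison the 6 arrays make 10 splits, which are too few for a share under 0.05. The real split was 1 of the 10 in each case, with 6438 genes in Pten knockout against wild type, 120 in double against Pten knockout and 6471 in double knockout against wild type. With limma the highest of the other splits gave 0 genes in each, with at most 124, 503 and 202 at an unadjusted p under 0.05. Each of those splits mixed arrays of both groups, so the group difference widened the spread within the parts. Their counts therefore do not show how many calls unchanged groups would give.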

How the results depend on the processing

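Across 21 alternatives, at most 19 of them for any result, 2636 values stayed the same: 1650 of lists and 801 of named genes kept their side of the threshold (and their direction where called), and 185 were mostly counts, which stayed within 1.5 times, or similarities, within the SD of pairs of arrays. Another 108 no longer passed (64 for lists, 44 for named genes), 44 lists newly passed, 19 counts or similarities moved, and 3 lists turned direction. The cause was not tested except where stated. Genes changed between double and Pten knockout numbered 120, against 182 with array weights, 48 at an adjusted p under 0.01, and 61 to 120 with 1 array left out (fewer samples): 61 without Pten knockout replicate 1, of which 56 were among the 120, 63 without replicate 2, 74 without replicate 3, and 61 without double knockout replicate 2. Other settings gave 90 to 153, with 93 under a replicate block (84 among the 120). Correlations of residuals between arrays of the same replicate number had a median of 0.0009 (-0.164 to 0.164). Between arrays of different numbers the median was 0.0254 (-0.212 to 0.206). These values gave no sign that replicate numbers pair the arrays, but so few arrays cannot exclude a pairing. The counts of changed genes against wild type stayed within 1.5 times of 6438 and 6471 under every alternative run. Those of at least 2-fold did not: 2208 became 1123 without the dimmest genes (fewer genes tested) and 3339 over every probe (more tests), 57 became 31 and 104, and 2214 became 1139 without the dimmest genes. An estimated correlation left 0, 0 and 0 lists called in Pten knockout against wild type, double against Pten knockout and double knockout against wild type (camera; 3, 3 and 3 at an unadjusted p under 0.05), and fry, which tests the members alone, called 27, 3 and 24. With 1 array left out, 7 to 14 lists were called between the knockouts, 14 without double knockout replicate 3. The lowest correlation between arrays of a group went from 0.980 to 0.976 without the dimmest genes. Androgen response (0.0048) and B and plasma cells (0.0278) turned direction with fry in Pten knockout against wild type. Fibroblast genes between the knockouts ranged from adjusted p = 2.1e-05, upward without double knockout replicate 3, to 0.960 with fry (0.764 at most with 1 array left out), and turned downward without double knockout replicate 2 (0.0174). The signal over background is unknown, since no detection call is given, and pseudocounts were not varied because values were already log2.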

Other observations

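The gene families below, grouped by symbol, and the comparison with genes that had risen, on separate arrays, were chosen only after the data were seen. Among 135 families with at least 8 measured members, chemokine genes were higher in Pten knockout than in wild type prostates: 9 of 11 Cxcl genes rose and 1 fell (median 3.34, camera adjusted p = 0.0354), and 8 of 9 Ccl genes rose (median 2.49, 0.0465), directions that held under quantile normalization and median centring. The mucosal chemokine Cxcl17 rose by 5.39, Cxcl16 by 3.34, Ccl3 by 4.53 and Ccl28 by 3.39, while Cxcl12 changed by -1.52. Keratin genes rose in 9 of 10 (median 1.81, 0.0192) and receptors of the tumour necrosis factor family in 8 of 11 (median 1.41, 0.0451), such as Krt6a by 2.59, Krt7 by 1.83 and Tnfrsf1b by 2.55, in the same direction under both scalings. Each of these calls was lost with an estimated correlation (adjusted p = 0.968 with an estimated correlation for the families).

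Of 19 genes whose symbols begin with Sec, 16 fell and 2 rose in the same comparison (median -0.41, camera adjusted p = 0.0060), with the coat proteins Sec24d at -1.47 and Sec24a at -0.88, Sec61g of the translocon at -1.19 and Sec16a at -1.11. The risen members, Sec14l1 (0.20) and Sec14l2 (0.43), belong to a family of lipid-binding proteins. Genes whose symbols begin with Rps fell in 14 of 22, with 1 higher (median -0.43, 0.0192), and those that begin with Rpl in 14 of 28, with 3 higher (median -0.28, 0.0463). Most encode ribosomal proteins, but the risen Rps6ka3 (0.69) and the fallen Rps6kb2 (-0.67) encode kinases, the fallen Rps19bp1 (-0.35) a binding protein, and some are pseudogenes. No direction of these families turned under quantile normalization or median centring. These calls too were lost (adjusted p = 0.968 with an estimated correlation). Between the knockouts, 1 of 8 Igkv genes, which encode immunoglobulin light chains, passed the test, Igkv4-72 at -2.25 (adjusted p = 0.0018). The median of the 8 was -1.23, below 0 under either scaling too, with Igkv4-91 at 0.68 (camera adjusted p = 0.0106; adjusted p = 0.991 with an estimated correlation). The fixed list of B and plasma cell markers had a median of -0.33 there and was not called (camera adjusted p = 0.0660).

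A further loss of the products of normal prostate when Pml is lost too was tested as a hypothesis. Over 223 genes that had fallen by at least 2 on the log2 scale in Pten knockout against wild type, the median change of double against Pten knockout was -0.06, with 128 below 0 and 95 above, and 21 called lower and 8 higher. Random sets matched on mean level reached a lowest median of -0.05 (share 1e-04, the smallest 10000 sets can give). The Pten knockout arrays enter both the choice of genes and the change measured, so the choice was repeated on 1 Pten knockout array at a time and the change measured against the other Pten knockout arrays. Genes that had fallen then had medians of -0.05, -0.11 and -0.06, and genes that had risen by as much -0.08, -0.09 and -0.04, so the fallen genes did not lie below the risen ones in each, and the hypothesis stays open.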
